A study of Mus musculus with 4 samples.

How the data were processed

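Tumours from wild-type and Mif-depleted 4T1 cells in BALB/c mice were dissociated, stained for CD45 and with propidium iodide, and sorted for CD45-positive, dye-negative cells before 10x Genomics library preparation, per the labels. Each sample combined 3 tumours, and the labels name 2 samples for each of 2 groups. Cell Ranger and Seurat with the mouse build GRCm38 (mm10) are named in the submitters' processing notes, without their roles. Versions, filters and the method of naming cell types are not given in the sources used here.

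The count table holds UMI counts per gene and cell as deposited, and every value used was a whole number of 0 or more. The part used here held 16383 cells and 4099 complete gene rows, followed by 1 incomplete row with values for 14020 cells that was left out of all levels. By symbol, 4067 rows matched GENCODE M21 on GRCm38, with 979, 1189, 789, 924 and 186 genes on chromosomes 1 to 5, and 32 did not match, 2 of them symbols turned into dates. The first row was Mrpl15 and the last complete row Gm1673. Coordinates in the text come from that annotation. Since later chromosomes were not analysed here, a cell's UMI total is not its depth, and mitochondrial transcripts were not analysed. Cell types are text labels deposited by the authors for 45781 barcodes.

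Barcodes end in a suffix from 1 to 4. No header or label assigns a suffix to a sample, so none was assigned, and pairs of suffixes shared only 24 to 42 barcode sequences. The planned tests between groups (of summed UMIs per sample, of cell numbers and of gene lists) were therefore not run. In their place, shares of cells were given per suffix with exact Clopper-Pearson 95% intervals. UMIs were summed over the cells of each type within a suffix and scaled to 10000 counted UMIs, with exact Poisson 95% intervals. Each type was set against all other cells of the same suffix, and 3 pairs of types were set against each other, with exact conditional binomial 95% intervals of the ratio. Cells are not replicates, so no p-value or standard deviation was computed, and intervals cover counting error only. All 13162 cells of suffix 1 and 26.9% of those of suffix 2 had counts. The largest difference in the share of a type between the cells of suffix 2 with and without counts was 2.30 percentage points, in neutrophils.

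The gene lists, cell type markers and the rule for naming genes were fixed before the data were examined. The rule asked for 50 or more UMIs over both sides and an interval excluding a 2-fold ratio, and then took the 10 highest and 10 lowest log2 ratios for the 3 names with the most cells and 5 and 5 for the others. It was written for groups and was carried over to cell types after the data were seen, as were the comparisons of cell types themselves, and the text names part of the genes it gave. The list members, markers and pattern genes were named in addition, some chosen after their values were seen. The authors' names may rest on some of the same genes, so a high level in a type is a description and not independent evidence for its name. Of 504 genes on 23 fixed lists, 124 were measured, and 22 lists had a member. The list of mitochondrially encoded transcripts had 0. Of 23 marker lists, 18 had a member. Those of mature regulatory and plasmacytoid dendritic cells, CD8 T cells, plasma cells and platelets had 0. The ribosomal list, with 8 genes measured, was highest in CD4_Tcm at 2069 and lowest in neutrophils at 112, and in UMIs per cell the CD4_Tcm log2 ratios to other cells of Rpl7 and Rps27 moved from 1.38 and 2.37 to -0.50 and 0.50. A count of 0 was given a floor of 3 counts. The results of 1 cell type name and of some genes are not reported here.

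The ratio procedure was tested on simulated counts in which 200 genes were changed. In the simulation of neutrophils, 86.0% of the genes raised 3-fold and 100% of those raised 6-fold were found, and in that of natural killer cells 24.0% and 71.4%. Of the genes lowered 6-fold, 97.9% and 6.00% were found. In small types such as natural killer cells, most lowered genes and most genes raised 3-fold therefore go unfound, while most raised 6-fold are found. Among 3323 unchanged genes in the simulation of natural killer cells, 3 were wrongly placed beyond a 2-fold ratio, and 0 in the other simulations. The simulated counts were Poisson draws, as the intervals assume, so few wrong calls were to be had and spread between cells was not covered. No doublet caller was run, and the labels do not say whether doublets were removed. Thinning drew 500 UMIs from each cell without replacement. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.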

Results

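Sorted CD45-positive cells from mouse mammary tumours were profiled by droplet single-cell RNA sequencing. The tumours grew in BALB/c mice from 4T1 cells, a transplantable mammary carcinoma line of that strain, which were either wild-type or depleted of Mif, the gene of macrophage migration inhibitory factor. Each group had 2 libraries, 4 in all. The deposited annotation gave 45781 barcodes, each with 1 of 23 cell type names and a suffix from 1 to 4. Suffixes 1, 2, 3 and 4 held 13162, 11961, 9317 and 11341 cells. No label or header tied a suffix to a library, so the question of how Mif depletion altered the immune infiltrate was not analysed here and no value below compares control with Mif-depleted tumours. UMI counts (unique molecules per gene and cell) were used for all 13162 cells of suffix 1, with 29567302 UMIs in all and a median of 1224.5 per cell, and for 3221 cells of suffix 2, with 8578852 UMIs and a median of 1712. They covered 4099 genes on chromosome 1 to part of chromosome 5. Mif itself and its receptor chain Cd74 were not analysed here. Levels are UMIs per 10000 UMIs of these genes, summed over the cells of a type in suffix 1 unless stated, and brackets hold exact 95% intervals that cover counting error only. There were no replicates behind these levels, and no test was run.

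Macrophages and neutrophils made up most of the annotated cells, and their shares differed between suffixes by more than counting error. Cells with the 5 macrophage names took 16.2%, 21.01%, 40.9% and 37.1% of suffixes 1 to 4, with exact binomial 95% intervals of 15.6% to 16.9%, 20.3% to 21.8%, 39.9% to 41.9% and 36.3% to 38.0%. Neutrophils, the phagocytes that carry the calprotectin subunits S100a8 and S100a9, took 43.4%, 27.0%, 25.9% and 11.1%, with a median of 26.5%. Among macrophages, Macro_Vegfa ranged from 6.62% to 18.6% and Macro_Maf from 5.60% to 15.6%, both highest in suffix 3. Monocytes ranged from 4.86% to 10.8% with a median of 6.58%, and dendritic cell names from 4.20% to 10.1% with a median of 5.94%. Without cDC1_Clec9a, whose leading genes are known from osteoclasts, the dendritic names took 2.95%, 5.19%, 4.24% and 5.11% of suffixes 1 to 4.

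Lymphocyte shares were lowest in suffix 3 for several names. B cells took 13.6%, 12.4%, 6.15% and 14.6% of suffixes 1 to 4, and CD4 T cells 8.45%, 8.65%, 2.55% and 10.0%. The central memory name CD4_Tcm had 12 cells in suffix 3, a share of 0.129%, against 1.94% to 2.54% in the other suffixes. Naive CD4_Tn cells ranged from 0.301% to 3.51% and regulatory CD4_Treg cells from 1.17% to 2.62%. Exhausted CD8_Tex cells took 4.00%, 8.36%, 3.81% and 8.47%, and natural killer cells 0.441%, 1.84%, 1.31% and 1.86%. Cells named cDC1_Clec9a made up 4.94% of suffix 2 and between 1.01% and 1.51% of the others. Epithelial cells ranged from 2.03% to 3.79% and fibroblasts from 0.837% to 1.35% although the sort selected CD45. With the suffixes unmatched to libraries, these are values of 4 samples of unknown group.

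**Figure D1:**
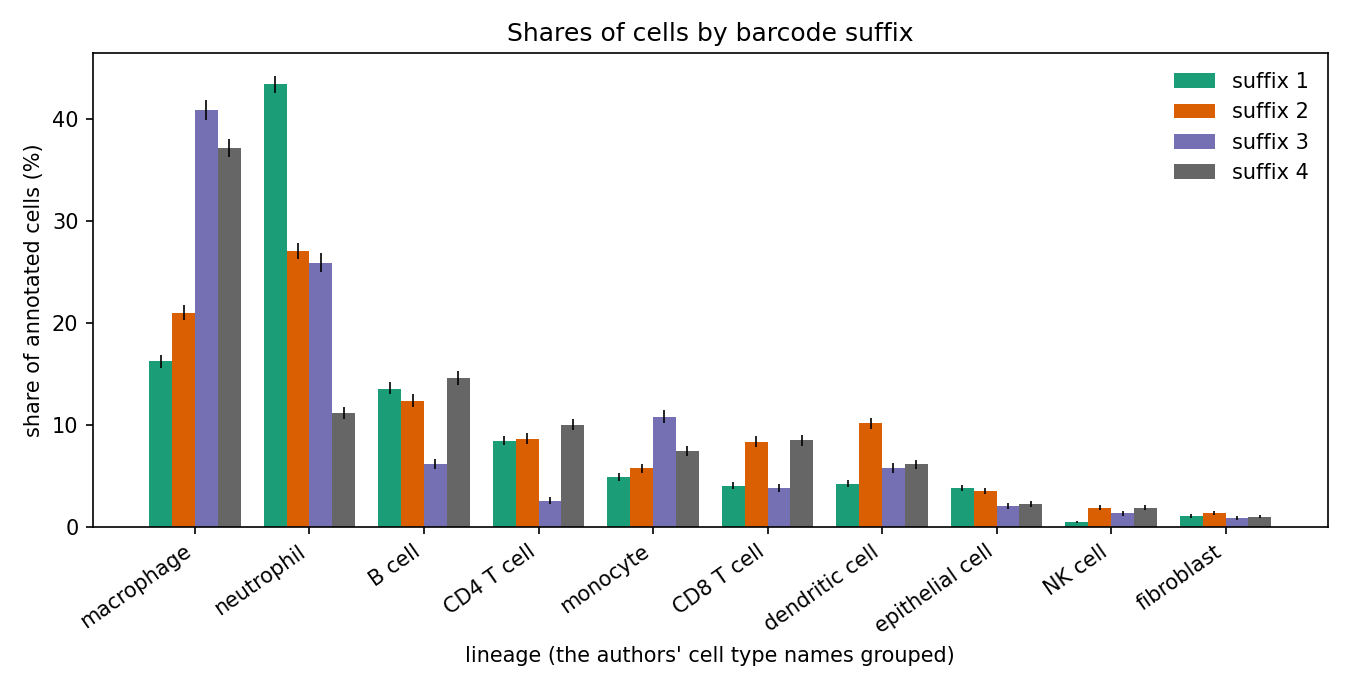
Bars give the share of annotated cells, in percent, in each of 10 lineages (the authors' names grouped) for the 4 barcode suffixes, and black lines give exact binomial 95% intervals. Neutrophils fall between 11.1% and 43.4% and macrophages between 16.2% and 40.9%.

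Neutrophils were set apart by S100a8 and S100a9, which lie near each other on chromosome 3 (GRCm38, 90668978 to 90670035 and 90692632 to 90695721). S100a9 stood at 3305 per 10000 UMIs in neutrophils and 239 in all other cells, and S100a8 at 2545 and 181, so that the pair took 58.5% of the neutrophils' counted UMIs. G0s2, an inhibitor of triglyceride lipase, stood at 88.3 against 8.23, a log2 ratio of 3.42 [3.40, 3.45], and the interleukin-36 gamma gene Il1f9 at 7.89 against 0.760. Of the 7 measured genes of the suppressive neutrophil list, 4 lay above a 2-fold ratio beyond counting error, among them the siderophore-binding Lcn2 (151 against 15.4) and the chemokine receptor Cxcr2 (11.3 against 1.27). Ptgs2 stood at 3.42 against 14.3, a log2 ratio of -2.06 that was -0.86 without S100a8 and S100a9 in the denominator and -0.50 in suffix 2. Of the 8 measured neutrophil markers, 7 lay above a 2-fold ratio beyond counting error. Among them were Csf3r, the G-CSF receptor gene, at 23.01 against 3.66 and the histidine decarboxylase gene Hdc at 15.6 against 1.98. Mmp9 stood at 17.3 against 21.1. Its log2 ratio of -0.29 was 0.92 without S100a8 and S100a9 in the denominator and -2.19 in suffix 2. Among the 10 lowest ratios were those of genes of fibroblasts, Serping1 (log2 ratio -8.68) and Col6a3 (-8.11). Because S100a8 and S100a9 fill the denominator, leaving them out raised every neutrophil log2 ratio by 1.21 and moved the ratios of the other names by -0.23 to -0.42. Scaling to UMIs per cell moved the median log2 ratio by between -1.87, in CD4_Tcm, and 1.72, in Macro_Mgl2, so levels here are relative to the counted UMIs of each name.

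Macrophage names differed in inflammatory, interferon and cell cycle genes. Macro_Maf led the macrophage marker list, of which all 5 measured genes lay above a 2-fold ratio. The complement genes C1qa, C1qb and C1qc stood there at 186, 130 and 114 against 32.5, 22.3 and 19.5 in other cells, close to the 183, 124 and 101 of Macro_Ccl12, and the mannose receptor gene Mrc1 at 11.6 against 2.11. Macro_Vegfa stood higher in Il1a (18.0 against 4.17, log2 ratio 2.11 [2.07, 2.16]), in Il6 (1.90 against 0.451), in the prostaglandin synthase gene Ptgs2 (31.6 against 7.69) and in Tnfrsf9 (7.97 against 1.73). Set directly against Macro_Maf, it was higher in Tnfrsf9 by 2.31 on the log2 scale [2.17, 2.46] and lower in Clspn, a gene of the DNA replication checkpoint (-2.34 [-2.85, -1.86]). It also held more of the neutrophil transcripts S100a8 (282 against 73.2) and S100a9 (388 against 108).

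Macro_Ccl12 led the interferon-stimulated list at 163 [157, 169] per 10000 UMIs in suffix 1 and 145 in suffix 2, with cDC2_Cd209a next at 60.6. Among its 12 measured members were the ubiquitin-like Isg15 (43.8 against 4.00), Ifi44 (21.1 against 1.33) and Ifi204 (17.7 against 1.74). Macro_Maf cells, with a median of 3652 counted UMIs, had an Isg15 UMI in 46.8%, and Macro_Ccl12 cells, with a median of 423, in 35.1%. The summed levels of Macro_Ccl12 do not show how many of its cells carry these genes. The name also led the interferon-gamma-inducible list (37.6), with Gbp7 at 9.24 against 2.41 and Gbp3 at 4.22 against 0.953, but their log2 ratios of 1.94 and 2.15 were 0.95 and 1.02 in suffix 2, where CD4_Treg led the list at 41.6. Of the 13 genes of the class II presentation list only 2 were measured, Ctss and Rfx5. Macro_Ccl12 led these as well, nearly all through the lysosomal protease gene Ctss, with Macro_Maf next at 99.4. Ctss stood at 115 against 34.1, a log2 ratio of 1.75 that was 0.99 in UMIs per cell, and Rfx5 at 0.171 against 0.161. Macro_Mgl2 led the cell cycle list at 64.3 [63.1, 65.5]. It also came second to neutrophils in S100a8 (499.5), S100a9 (711) and Lcn2 (54.9) in suffix 1, but lay behind Mono_Nr4a1 in S100a8 and epithelial cells in Lcn2 as well in suffix 2, and had the neutrophil granule gene Fcnb at 0.605 against 0.0440. Nusap1 and Tpx2, which act on the mitotic spindle, stood at 5.41 and 5.66 against 0.544 and 0.630, and the ubiquitin-conjugating enzyme gene Ube2c at 12.1 against 1.30. The cycling marker Stmn1 stood at 23.9 against 4.57, but was highest in B cells in suffix 2 (21.8). Of the 14 measured cell cycle genes, 11 lay above a 2-fold ratio in Macro_Mgl2 in suffix 1, and Pcna, Mcm6 and E2f1 did not. Pcna and Mcm3 were highest in CD8_Tex in suffix 1, at 13.1 and 3.79.

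Monocyte names differed in Thbs1 and Chil3. Thbs1, which encodes thrombospondin 1, stood at 57.2 in Mono_Ly6c2 against 3.17 in other cells, a log2 ratio of 4.17 [4.12, 4.22], and at 39.8 in Mono_Itgal. In suffix 2, Thbs1 stood at 32.6 in Mono_Ly6c2 and 76.8 in Mono_Itgal, which had 5 cells there. The thrombomodulin gene Thbd stood at 3.66 against 0.273. Chil3, a chitinase-like secreted protein, stood at 55.1 in Mono_Nr4a1 against 3.06, and at 10.4 in suffix 2. Of the 26 genes of the alternatively activated list 4 were measured, and Mono_Nr4a1 led them at 78.6, mostly through Chil3. The list stood at 39.3 in this name in suffix 2. In Mono_Nr4a1, Klf4 stood at 22.6 against 7.95 and Mrc1 lower, at 0.466 against 3.11. The monocyte marker Fn1 stood there at 62.4 against 28.7, a log2 ratio of 1.12 that was 0.06 in suffix 2. Set against Mono_Nr4a1, Mono_Ly6c2 was higher in the podoplanin gene Pdpn by 4.11 on the log2 scale [3.21, 5.19] and in the atypical chemokine receptor gene Ackr3 by 3.88 [3.05, 4.85]. Mono_Ly6c2 led the glycolysis list at 47.6 and the hypoxia list at 20.3. The glucose transporter gene Slc2a1, on both lists, stood at 18.7 against 7.78, a log2 ratio of 1.27 that was 0.93 without S100a8 and S100a9 in the denominator and 1.00 in suffix 2. It made up most of the hypoxia list, where Car9 stood lower (0.0523 against 0.221) and Plod1 at 1.53 against 1.28, while the enolase gene Eno1 stood at 23.1 against 13.02. Mono_Itgal, with 41 cells, led the inflammatory macrophage list at 265 [257, 274], with Il1b at 167 against 77.6, and Macro_Vegfa followed at 254. In suffix 2, Mono_Itgal led the glycolysis list at 44.2 and the alternatively activated list at 48.25.

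Among T cells, naive and regulatory names carried contrasting programmes. CD4_Tcm led the naive and memory list at 138 [132, 143], followed by CD4_Tn at 122. In CD4_Tcm the transcription factor gene Lef1 stood at 35.9 against 0.818, Dapl1 at 27.8 against 0.267 and the survival gene Bcl2 at 23.9 against 1.13. CD4_Treg led the activation list at 214 [208, 220] and the checkpoint list at 154 [148, 159]. In it Ctla4, the inhibitory receptor, stood at 96.0 against 1.54, the inducible costimulator gene Icos at 46.2 against 0.820 and Tnfrsf4 at 38.3 against 0.641. On the same lists, Cd244a stood lower (0.0493, which was 1 UMI, against 0.608), and Cd44 (14.7 against 14.1), Nr4a2 (10.4 against 6.80), Il2 and Cd160 (1 UMI each) did not differ by 2-fold beyond counting error. All 6 measured regulatory T cell markers lay above a 2-fold ratio, among them the transcription factor gene Ikzf2 (69.1 against 1.18) and Il2ra (23.8 against 0.507). Of the CD4 T cell markers, Icos and Lef1 were measured, and Lef1 stood at 2.76 in CD4_Treg against 0.996. Set against CD4_Tn, CD4_Treg was higher in Il2ra by 7.90 on the log2 scale [6.34, 10.2], 4.63 in suffix 2, and lower in Dapl1 (-5.20 [-6.52, -4.14]) and Bcl2 (-4.29 [-5.08, -3.59]). Il1rl1, which encodes the interleukin-33 receptor, had 306 UMIs in CD4_Treg and 0 in CD4_Tn, a ratio of 151 with 3 counts put in place of the 0.

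CD4_Th, with 56 cells in suffix 1, was higher in Penk (29.9 against 0.161) and in Gata3 (22.5 against 0.619), a transcription factor gene of type 2 responses. The Penk log2 ratio was 7.53 in suffix 1 and 0.50 in suffix 2. This name also led the 2 measured of 8 group 2 innate lymphoid markers at 31.8. In suffix 2 CD4_Treg led them at 32.4, with CD4_Th at 29.1. CD4_Th led the gamma delta T cell markers, where Il17a stood at 2.10 in suffix 1 and 22.96 in suffix 2. It led the stress list at 270, with cDC2_Cd209a next at 264. On that list Dnaja1 stood at 122 against 26.2 and Btg2 at 78.5 against 21.6. Jun and Atf3, the other measured members, had log2 ratios of 0.39 and 0.26, and of -0.53 and -0.66 in UMIs per cell. CD4_Tfh was higher in Tnfsf8 (14.1 against 0.378) and, with 9 UMIs, in Tox2 (log2 ratio 5.64, and 2.58 in suffix 2). Natural killer cells were led by the chemokine gene Xcl1, at 86.8 against 0.705, a log2 ratio of 6.94 [6.79, 7.09] in suffix 1 and 7.03 in suffix 2. Xcl1 was the only measured chemokine on that list and the only measured natural killer marker. The cytotoxic list was highest in natural killer cells (99.4), mostly through Xcl1, with Fasl at 4.14 against 0.108, Cst7 at 3.94 against 0.372 and Zeb2 lower, at 4.54 against 10.9. In suffix 2, Cst7 was highest in CD8_Tex (3.67). Their Car2, on the erythroid marker list, stood at 21.3 against 0.638, and at 11.6 in suffix 2.

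CD8_Tex cells were higher than all other cells together in Xcl1 (7.65 against 0.316), in the inhibitory receptor gene Pdcd1 (4.38 against 0.274) and in Cd160 (0.656 against 0.0285). Pdcd1 was higher still in CD4_Th (17.6) and CD4_Treg (7.88) in suffix 1, but highest in CD8_Tex (6.50) in suffix 2. Cd160 was highest in natural killer cells (4.14). In CD8_Tex, Il17a stood above the other cells in suffix 1 (log2 ratio 4.06) and below them in suffix 2 (-1.34). The CD8_Tex cells also carried macrophage transcripts, with the 3 C1q genes summed at 202 [200, 204] against 10.7 [9.97, 11.4] in the pooled CD4 names. Of the 527 CD8_Tex cells, 253 had 5 or more C1q UMIs. The 7 T cell signalling genes, which CD4_Treg led at 126, stood in these 253 cells at 14.4 [13.8, 15.0] and in the 106 cells without C1q UMIs at 50.3 [47.2, 53.6]. Macro_Maf cells with 5 or more C1q UMIs stood at 0.911. Median counted UMIs were 3292 in CD8_Tex and 590 to 1013.5 in the CD4 names.

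**Figure D2:**
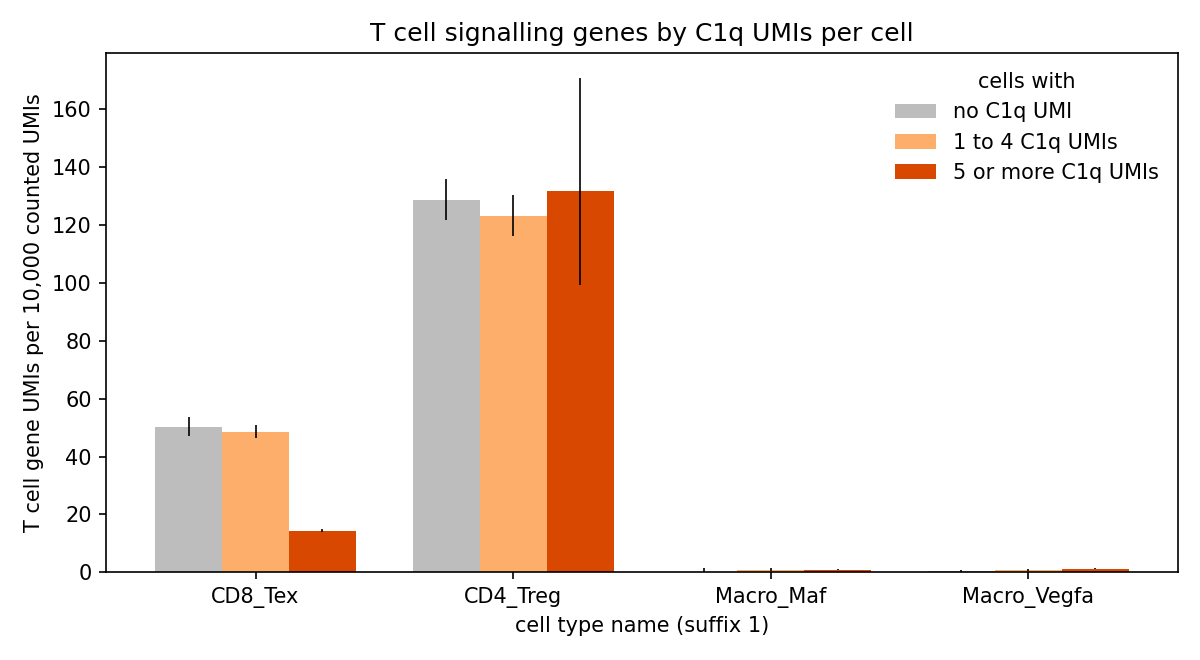
Bars give the summed level of 7 T cell signalling genes, in UMIs per 10000 counted UMIs, for suffix 1 cells of 4 names split by their C1q UMIs, with exact Poisson 95% intervals as black lines. In CD8_Tex the level is 50.3 without C1q UMIs and 14.4 with 5 or more, while Macro_Maf stays under 1.

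B cells were identified by Pax5, the B lineage transcription factor gene, at 10.2 against 0.162, and by Fcmr, the IgM receptor gene, at 10.9 against 0.133. Complement receptor gene Cr2 stood at 6.15 against 0.0939 and Bank1 at 10.4 against 0.221, with log2 ratios of 6.03 and 5.55 in suffix 1 and 5.54 and 5.62 in suffix 2. The mast cell marker Cpa3 stood at 0.659 in B cells. Among the lowest ratios was that of the fibroblast gene Col3a1 at -5.18 [-5.62, -4.76].

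Dendritic cell names differed in which genes led them. In cDC1_Ccl22, Batf3, a transcription factor gene of conventional dendritic cells, stood at 9.02 against 0.286. Both measured genes of the list of costimulatory and coinhibitory molecules lay above a 2-fold ratio there, Cd40 at 10.7 against 0.510 and Tnfsf4 at 4.02 against 0.0316. The class I light chain gene B2m stood at 226 against 76.5, a log2 ratio of 1.56 that was 0.85 in suffix 2, while Pdia3 stood at 7.25 against 8.93, and the fatty acid-binding gene Fabp5, the 1 member of 8 above a 2-fold ratio on the lipid list, at 77.0 against 8.18. The eosinophil marker Prg2 stood at 3.23 against 0.00680, with 53 UMIs, a fold of 475 that was 27.8 in suffix 2. In cDC2_Cd209a, Ifi205 stood at 3.09 against 0.132, whereas Sirpa, a marker of that type, was highest in macrophage names. Sirpa stood at 12.5 in Macro_Ccl12 and 12.1 in Macro_Maf, and was highest in Macro_Vegfa in suffix 2, at 13.3.

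Cells named cDC1_Clec9a were led by Ctsk, the gene of the collagen-degrading protease cathepsin K (chromosome 3, 95499256 to 95509362, GRCm38), at 513 against 5.26, a log2 ratio of 6.61 [6.58, 6.63] in suffix 1 and 5.92 in suffix 2. Slc9b2 stood at 27.5 against 0.297 and the proton pump subunit gene Atp6v0d2 at 38.5 against 0.591. Mmp9, on the neutrophil granule list that this name led at 296, stood at 294 against 11.9 while Lcn2, Chil3 and Padi4 of that list lay below a 2-fold ratio. This name led the oxidative phosphorylation list at 238 [235, 242], with Sdhb at 16.5 against 2.93. All 9 measured genes were higher, though Atp5e (log2 ratio 1.10) and Uqcrh (1.16) stood at 0.70 and 0.76 without S100a8 and S100a9 in the denominator. In suffix 2 they stood at 0.89 and 1.03, neither above a 2-fold ratio beyond counting error. The name pDC followed on that list at 157 and had Atp6v0d2 at 13.9 against 1.23 and Nrp2 at 18.5 against 1.70, with log2 ratios of 3.50 and 3.44 that were 1.44 and 1.98 in suffix 2. Ptprc, which encodes CD45, stood at 6.63 in cDC1_Clec9a and 24.7 in cDC2_Cd209a.

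Epithelial cells and fibroblasts were marked by genes with few UMIs elsewhere. Fermt1, an integrin adaptor gene, stood at 2.77 in epithelial cells against 0.00247, and Gpa33 at 3.97 against 0.00494. In fibroblasts Podn had the highest ratio, at 5.47 against 0.000344, which was 1 UMI. Col3a1 stood at 575 against 0.130, Postn at 64.7 against 0.0189 and Serping1 at 57.6 against 0.00688, so that all 3 measured fibroblast markers lay above a 2-fold ratio. The endothelial marker Egfl7 stood at 2.01 against 0.0602 in fibroblasts. Of the tumour epithelial markers, Lcn2 was higher in neutrophils (151), and the 2 measured markers together stood at 135 in epithelial cells. Ptprc stood at 2.34 [2.08, 2.63] in epithelial cells and 3.55 [3.04, 4.11] in fibroblasts. After each cell was thinned to 500 counted UMIs, 6.41% of 343 epithelial cells had a Ptprc UMI, with 156 shallower cells left out, against 70.2% of 5126 neutrophils with 586 left out. The unthinned shares were 16.6% and 90.9%, at median counted UMIs of 826 and 1120.

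**Figure D3:**
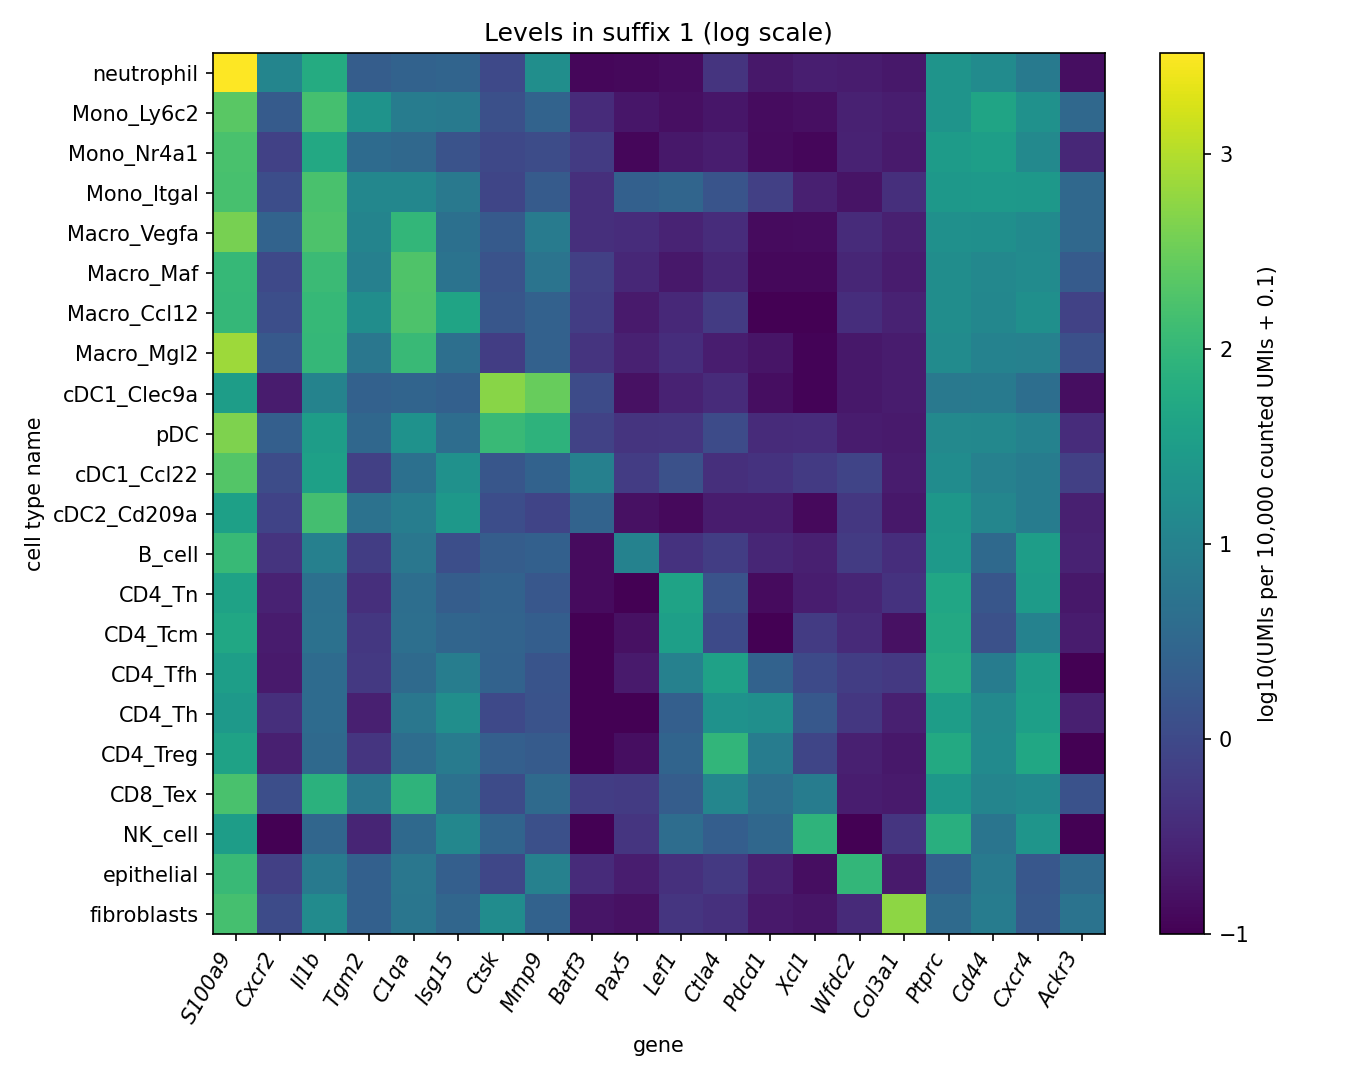
Colour gives the level of each gene in suffix 1 on a log10 scale (UMIs per 10000 counted UMIs, plus 0.1) for the cell type names shown. S100a9 reaches 3305 in neutrophils, Ctsk 513 in cDC1_Clec9a and Col3a1 575 in fibroblasts, and Ptprc is lowest in epithelial cells at 2.34.

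The receptors of MIF that were measured were spread over different cells. Cd44 was highest in Mono_Ly6c2 at 43.7 [42.2, 45.2], followed by Mono_Nr4a1 at 33.6, and lowest in CD4_Tcm at 1.25. Cxcr4 was highest in CD4_Treg at 49.8 [46.8, 53.0], with CD4_Th at 35.7 and B cells at 33.2, and stood at 6.88 in neutrophils. Cxcr2 was highest in neutrophils at 11.3 [11.1, 11.5] and Ackr3 in fibroblasts at 5.13 [4.52, 5.80]. In suffix 2, Cxcr4 was highest in CD4_Th at 33.3, followed by CD4_Treg at 28.1, with B cells at 16.2. Ackr3 was highest there in the 5 Mono_Itgal cells at 9.51, followed by fibroblasts at 6.51, and Cd44 in Mono_Ly6c2 stood at 51.8. The 4 genes together were highest in Mono_Ly6c2 at 67.9, where Cd44 and Ackr3 lay above a 2-fold ratio and Cxcr2 below it.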

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

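The incomplete last row of the count table, for Nat8l, was used in no level, and it held 111 UMIs over the 14020 cells with a value, above the 3 counts that a value of 0 allows.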

How the results depend on the processing

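No paired analysis was possible because no label ties a barcode suffix to a group or a replicate and no test between groups was run. For the same reason the alternatives set out beforehand for those tests (other size factors, another count model, other count filters, libraries thinned to the smallest, other share models, replicates left out, a filter on detected genes and mitochondrial UMIs, other list tests and the interaction) were not run. Apart from the denominator without neutrophils, all settings here were chosen after seeing the data. Leaving out each suffix in turn (leave-one-out) gave median shares of 21.01% to 37.1% for macrophages, 4.00% to 8.36% for CD8 T cells, 5.73% to 7.44% for monocytes, 2.23% to 3.50% for epithelial cells and 1.31% to 1.84% for natural killer cells. For neutrophils, B cells, CD4 T cells, dendritic cells and fibroblasts the medians stayed within counting error. Such a median is always a middle share, so it cannot respond to the extreme suffixes and does not show that shares were alike. Neutrophils still ranged from 11.1% to 43.4%. Over cells other than neutrophils the medians were 35.3% for macrophages, 16.7% for B cells, 11.6% for CD4 T cells, 8.30% for CD8 T cells, 8.48% for monocytes, 7.59% for dendritic cells, 3.77% for epithelial cells, 1.93% for natural killer cells and 1.49% for fibroblasts. The differences between suffixes changed as well. Without neutrophils, macrophages took 28.7%, 28.8%, 55.2% and 41.8% of suffixes 1 to 4, and the highest B cell and CD4 T cell shares were in suffix 1 (24.0% and 14.9%) and no longer in suffix 4. Without cDC1_Clec9a the dendritic cell median was 4.67%. The 300 named gene ratios were chosen as extremes, so that keeping their sign is no test. Outside their counting intervals lay 162 of them in suffix 2, 99 in UMIs per cell, 75 after thinning to the smaller UMI total, 68 without S100a8 and S100a9 in the denominator and, of the 240 tried, 36 without 2 names that may hold doublets, and a minimum of 20 UMIs cannot move a ratio. In addition 4 reversed in suffix 2, with log2 ratios of -1.34 for Il17a in CD8_Tex, 0.24 for Wfdc2 in Mono_Itgal, -0.11 for Serpinb2 in Mono_Ly6c2 and -0.19 for Atp6v0d2 in Macro_Vegfa against Macro_Maf, and the cause was not tested. A count of 0 in suffix 2 entered at the floor of 3 counts, so this number may miss reversals. Tox2 in CD4_Th, for example, had 0 UMIs there against 32 in other cells and kept a log2 ratio of 3.85.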

Other observations

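The 4 suffixes had macrophage shares of 16.2%, 21.01%, 40.9% and 37.1% and neutrophil shares of 43.4%, 27.0%, 25.9% and 11.1%, and no group was read from either. Ribosomal protein genes took 2069 per 10000 counted UMIs in CD4_Tcm and 112 in neutrophils. Between CD4_Treg and CD4_Tn, the interleukin-10 gene Il10 had 131 UMIs and 1, a log2 ratio of 7.60 [5.10, 12.9] in suffix 1 and 2.47 in suffix 2.

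In the patterns weighed here, the tests of a shifted column of names, of free RNA in cDC1_Clec9a and CD8_Tex, of separate cells as part of CD8_Tex and of doublets in epithelial cells and fibroblasts were chosen only after the result was seen. No biological explanation was tested, since no cell was placed in a group.

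The cells named cDC1_Clec9a were led by genes known from osteoclasts. The 7 such genes had a median ratio to other cells of 24.8 in suffix 1 and 32.6 in suffix 2. The lowest of the 7 stood at 6.78 and 5.29. High ratios were the outcome set against free RNA shared by all cells, but they restate the pattern, so this test cannot decide on free RNA. A shift of all names against the barcodes is argued against by the 4 of 5 measured bracketed genes that were highest under their own name. Ctsk was next highest in pDC, at 116 against 513, and these levels restate the pattern, so that doublets stay open. Whether the name itself is backed cannot be told apart. For 5 genes known from type 1 conventional dendritic cells, the median ratio was 2.19 in suffix 1 and 1.20 in suffix 2. Neither bound set for both suffixes was met. Together these genes were highest in cDC1_Ccl22 (17.5), followed by cDC2_Cd209a (14.7). Batf3 stood at 0.965 in cDC1_Clec9a against 9.02 in cDC1_Ccl22, whereas Ppt1 stood at 6.73 against 1.40. In suffix 2 the ratios to other cells of Rab7b and Dpp4 were 0.165 and 0.581, and those of Batf3, Ppt1 and Ifi205 lay between 1.20 and 1.86. Macrophage-lineage cells with an osteoclast-related programme remain a hypothesis, as Xcr1 and Clec9a were not analysed here.

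T cell and C1q transcripts met in cells named CD8_Tex. Cells with 5 or more C1q UMIs kept 0.287 of the T gene level of cells without C1q UMIs in suffix 1, near the lower bound of 0.25 set for doublets. In suffix 2 they kept 0.427 [0.387, 0.471]. These values argue against separate macrophages and T cells as the whole of this name, for which a ratio under 0.1 was set. As a part they stay open. After thinning, 30.9% [26.9, 35.2] of cells had both transcripts in suffix 1 and 30.4% [24.9, 36.4] in suffix 2, where independence gives 40.1% and 33.4%. This cannot decide, since doublets with a lower T gene level would also lose T UMIs on thinning. A T gene UMI was found in 90.9% of the CD8_Tex cells with 5 or more C1q UMIs in suffix 1 and 96.2% in suffix 2. For Macro_Maf cells with as many C1q UMIs the shares were 17.7% and 14.1%, at median counted UMIs in suffix 1 of 3809 against 5447. These shares argue against plain macrophages as most of those CD8_Tex cells. T cell and macrophage doublets may account for part of the name CD8_Tex. CD4_Treg gave a ratio of 1.02 from 3 cells with 5 or more C1q UMIs, too few to show whether a high ratio is specific to doublets. The C1q level in CD8_Tex was 18.95 times that of the CD4 names in suffix 1. This ratio restates the levels given in the Results, so it is no separate test. Free RNA shared alike by all cells would not give it. Summing a mean CD8_Tex cell without C1q and a mean Macro_Maf cell gave a T gene level of 16.1 beside the measured 14.4 in suffix 1 and 18.1 beside 21.7 in suffix 2. Both sums lay outside the counting intervals of the measured levels, 1 above and 1 below. The C1q level of the sum was 298 beside 273 in suffix 1 and 276 beside 214 in suffix 2. Mean counted UMIs were 5788 beside 6282 and 5516 beside 6820. Uptake of T cells by macrophages was not tested.

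Epithelial cells and fibroblasts occurred in every suffix of a CD45 sort. Their Ptprc level was 0.125 of that in other cells in suffix 1 [0.114, 0.137] and 0.0799 in suffix 2, below the bound of 0.25 set for doublets with CD45-positive cells. Carry-over through the sort gate was not tested.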
